A study of Mus musculus with 4 samples.

How the data were processed

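Cells were taken from mice of both sexes. Per the labels' protocols, the virus was injected at 8 weeks of age, 2 µl per eye, 2 weeks before the crush, and cells were collected 2 weeks after it. Per the labels' protocols, 10 retinas per condition were pooled, cells were panned with Thy1 and sorted for mCherry, about 5000 cells went into each replicate, and about 40% of ganglion cells were transduced. Polyadenylated RNA was sequenced in paired reads of 100 bases. Nothing in the labels says that the 2 libraries of a group came from separate animals.

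The values are whole-number counts per gene as deposited by the authors, for 78334 versioned Ensembl gene identifiers and 4 columns. Per the submitters' processing notes, the tools named were Trimmomatic 0.39, HISAT2 2.2.1, SAMtools 1.10, Cufflinks, Cuffnorm and Cuffdiff, with the mouse build GRCm39. The read counter, the annotation release and the strand setting are not given in the sources used here, so a gene and its antisense or overlapping partner cannot be told apart. The columns named for mCherry were taken as the scramble shRNA because the other columns name miR132. This rests on exclusion, since both vectors express mCherry, and every direction depends on it.

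The reference at hand was GENCODE M21, of an older build, so no coordinates are given. Gene names were found for 51486 identifiers, and unnamed ones held 0.433% to 0.437% of the counts. The seed-match test had been planned only for a reference of the same build. It was run on the transcript sequences of M21 after the data were examined, which departs from that plan. A 3' UTR was available for 10395 of the tested genes, 91.0%.

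Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, with DESeq2 1.42.0 as an alternative, and Python 3.11.15 was used for sequences and plots. Genes passed edgeR's filterByExpr, which kept 11427 genes with 98.6% of the counts. Libraries were scaled by TMM, and groups were compared with glmQLFit (legacy set to FALSE) and glmQLFTest, with Benjamini-Hochberg adjustment over all tested genes. Folds of single genes are ratios of CPM of summed counts, scaled by TMM. Levels of summed lists use library totals and all members with an identifier, tested or not. A gene with 0 counts in a group is given as a bound against 3 counts over the group. Gene lists with at least 5 tested members were tested with camera (preset correlation 0.01) on voom values, with camera at an estimated correlation, and with fry. List medians were also set against 10000 random lists matched on mean expression in 20 bins. Lists, tests and the rule for named genes were fixed before the data were examined.

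The rule named the 12 highest and 12 lowest genes by log2 fold change among those with an adjusted p under 0.05, a mean of at least 5 CPM and both libraries of one group on the same side of both of the other, and up to 4 called members of each list. The text gives a part of those members. C1qb and Olfml3 were named after their values were seen. The set of 47 leukocyte markers was added after the sum over 45 had been seen. Some results of the marker and metabolic lists are not reported here.

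Agreement of libraries was tested with a chi-square test of counts over genes. In simulated counts with sampling noise alone, for this comparison and 11427 genes, the test recovered 14%, 52%, 58% and 92% of 50 genes each changed by 1.25, 1.5, 2 and 4-fold, with 1 false call. In simulated pools with no effect, each drawn as 2 libraries, it called 27, 1022, 2404 and 4021 genes at a coefficient of variation of 0.05, 0.1, 0.15 and 0.2 between pools. The correction for GC content and length used spline fits per library with 4 degrees of freedom and was chosen after the data were examined.

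Alternatives covered other scaling factors, low-count filters, tests, thresholds, left-out libraries, thinned counts and a replicate block. The planned filter of 5 CPM in 2 libraries was meant to be stricter than filterByExpr and was looser at this depth, keeping 11708 genes. No coefficient of variation between animals can be measured here.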

Results

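Messenger RNA was counted in cells panned and sorted as mouse retinal ganglion cells, the neurons whose axons form the optic nerve. They were taken 2 weeks after an optic nerve crush. The eyes had received an adeno-associated virus of serotype 2 that expressed mCherry together with either an anti-miR132-3p shRNA, a hairpin directed against the microRNA miR-132-3p, or a scramble shRNA as the control. The counts table held 2 libraries per group. Library totals were 1845090 and 1846637 counts with the scramble shRNA and 1732416 and 1731199 counts with the anti-miR132-3p shRNA.

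The 2 libraries of each group differed by no more than the sampling noise of their counts. The chi-square per degree of freedom over genes was 1.02 for the scramble pair (p = 0.095) and 1.00 for the anti-miR132-3p pair (p = 0.49), against 4.01 to 4.03 for the 4 pairs across groups. The totals of a pair differed by 0.0838% and 0.0703%. Each pair was therefore counted as 1 sample, so that each group has n = 1, and no SD can be given and no difference between the groups has a replicate check. Values below are summed over a pair, in CPM, the count scaled to a common library size, and the 95% intervals of folds are exact (Clopper-Pearson) and cover counting error only. The p-values compare the reads of these libraries, not the conditions. A count of 3 in 1 library corresponds to 1.62 to 1.73 CPM. Where a group had 0 counts, the fold is given against 3 counts over the group, with the lower end of the exact 95% interval, which is the stricter bound, beside it.

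The targeted microRNA cannot be checked in these libraries. Mir132 and Mir212, the genes of the microRNA cluster, had 0 counts in all 4 libraries, and a library of polyadenylated RNA does not measure mature microRNA.

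The comparison of the anti-miR132-3p with the scramble shRNA asks which transcripts differ in these sorted cells when miR-132-3p is targeted. The libraries also held counts of amacrine, Müller glia and rod markers, given below, so a change need not lie in ganglion cells. Genes of the interferon response led the higher side. Ifit1, an interferon-induced RNA-binding protein, was at 136 CPM against 3.32 CPM, 40.9-fold higher (23.2 to 79.8). Irf7, a transcription factor of the interferon pathway, had 0 counts with the scramble shRNA and 50 with the anti-miR132-3p shRNA, at least 17.5-fold higher against 3 counts over the group and 13.7-fold by the lower end of the exact interval. On the lower side, Spp1, which encodes osteopontin, was at 21.5 CPM against 140 CPM, 6.50-fold lower (5.09 to 8.42), and Sag, the rod arrestin gene, had 2 counts against 131.

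Of 11427 genes tested, edgeR's quasi-likelihood test called 1540 higher and 1183 lower at a Benjamini-Hochberg adjusted p under 0.05, and 451 and 92 of these changed by at least 2-fold. These counts rest on a spread shared across genes and measured within the pairs: when 1 library was left out, whichever it was, edgeR's quasi-likelihood test called 0 genes, with 2652 to 2767 genes at an unadjusted p under 0.05, limma-voom called 0, edgeR's likelihood ratio test 1893 to 1971 and DESeq2 160 to 247. With no low-count filter the quasi-likelihood test called 1 higher and 2 lower, and in simulated pools with no effect and a coefficient of variation of 0.15 between pools it called 2404 genes.

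Among the 12 highest genes, Gbp2b had 70 counts against 0, at least 24.4-fold higher against 3 counts over the group (exact lower end 19.4), and Ifi44 had 49 against 0, at least 17.1-fold higher (exact lower end 13.4). Iigp1, an interferon-induced GTPase, had 60 counts against 1, and Gbp2 had 47 against 1. Rtp4 had 54 counts against 2, 28.3-fold higher (7.46 to 239). Usp18, a protease that removes ISG15 from proteins, was 21.4-fold higher (8.86 to 67.2), and Gbp3 was 14.8-fold higher (7.80 to 31.5). Cd74, the invariant chain of class II antigen presentation, was 26.4-fold higher (11.0 to 82.7). Ctss, the protease cathepsin S, had 51 counts against 2, and Cxcl13, a chemokine, was 10.5-fold higher (6.08 to 19.8).

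Among the 32 lists of genes fixed before the data were examined that had at least 5 tested members, the interferon response had the highest median. The list of other leukocyte markers, with 2 tested members, Cd74 and H2-Ab1, had a median log2 fold change of 3.82. Of 31 interferon response members tested, 29 were called higher and 0 lower, and 29 were called higher when adjusted over the list alone. The median log2 fold change of the interferon response was 2.22, at percentile 100 among 10000 random lists matched on expression. The summed level of all 47 members with an identifier, tested or not, was 503 CPM with the scramble shRNA and 1687 CPM with the anti-miR132-3p shRNA. This sum was 3.35-fold higher (3.18 to 3.53). B2m, the light chain of class I molecules, rose from 52.9 to 245 CPM. Xaf1 and Trim30a each had 30 counts against 0, at least 10.5-fold higher against 3 counts over the group (exact lower end 8.00). Markers of microglia and other leukocytes, leaving out Ctss, Cd74 and the class II genes, gave values that depended on which were summed. Over 45 genes they held 136 counts against 26, 5.58-fold higher (3.65 to 8.84), and with Cd68 and Olfml3 added 157 against 76, 2.2-fold higher (1.66 to 2.94). The whole fixed microglia list, led by Lgmn, was at 290 against 294 CPM. C1qb, a complement gene, had 17 counts against 0, and Cd68, a lysosomal gene of phagocytes, had 16 against 42.

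**Figure D1:**
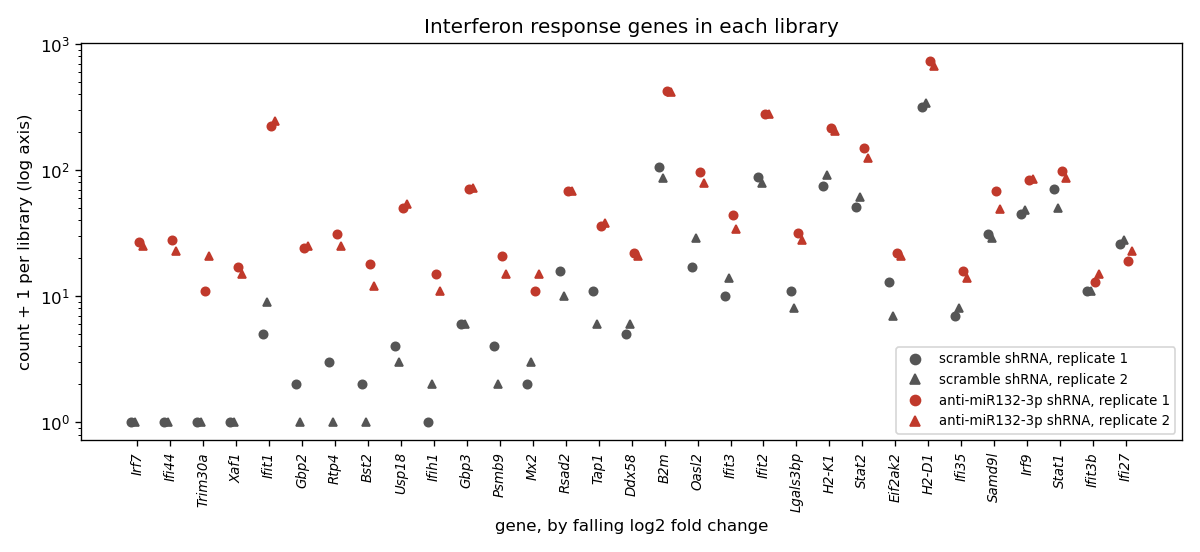
Count plus 1 in each of the 4 libraries (log axis) for the 31 tested genes of the interferon response list, ordered by falling log2 fold change, with grey for the scramble shRNA and red for the anti-miR132-3p shRNA, circles for replicate 1 and triangles for replicate 2. Of the 31 genes, 29 were called higher with the anti-miR132-3p shRNA.

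Genes that miR-132-3p is reported to target were not higher as a group. Of 32 tested, 4 were called higher and 8 lower, or 4 and 9 when adjusted over the list alone. The median log2 fold change was -0.14, at percentile 4.48 of matched random lists, and camera did not call the list (adjusted p = 0.060). After the correction for GC content and gene length the median was -0.10, at percentile 2.73. Camera then called the list lower (adjusted p = 0.042). Mmp9, a matrix metalloproteinase, was 2.13-fold higher (1.8 to 2.52) and Sema4d, a semaphorin, 2.07-fold higher (1.39 to 3.12). Sox11 was at 381 against 536 CPM, 1.41-fold lower (1.31 to 1.51), and Sox4 was 1.44-fold lower (1.16 to 1.8). The 1467 tested genes with a seed match of miR-132-3p in the annotated 3' UTR (the 8mer GACTGTTA or the 7mer-m8 GACTGTT) had a median log2 fold change of 0.0056. Sets of genes without one, matched on expression and 3' UTR length, had a mean median of 0.036 (shift -0.03, at percentile 0.11 of matched sets). Of the 1467 genes, 211 were called higher and 167 lower. Camera did not call the set (direction up, unadjusted p = 0.89). With matching on 3' UTR length and GC content, and no longer on expression, the shift was -0.0101 at percentile 9.27. With the GC and length correction it was -0.0092 at percentile 11.75, and both values lay inside the central 95% of matched sets. Of 299 shuffled heptamers, 256 gave a shift above that of the real one, and the central 95% of the shuffles, -0.04 to 0.02, held it. Sites for the scramble insert gave shifts of -0.04 at percentile 0.64 and 0.07 at percentile 99.8 on its 2 strands.

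Markers of ganglion cells were mixed, with more lower than higher. Of 27 ganglion cell markers tested, 3 were called higher and 10 lower, with a median of -0.24 at percentile 0.11. Thy1, the surface antigen used for panning, was 1.47-fold higher (1.34 to 1.61) and Tubb3 1.42-fold higher (1.30 to 1.55), whereas Pou4f1 was 1.47-fold lower (1.13 to 1.92) and Satb1 1.48-fold lower (1.14 to 1.92). Of 16 subtype markers, 1 was called higher and 8 lower, with a median of -0.23. Foxp2 was 2.81-fold lower (1.56 to 5.30) and Eomes 2.65-fold lower (1.2 to 6.46). Neurodevelopmental transcription factors had 1 of 25 members higher and 11 lower, with a median of -0.40 at percentile 0, and Neurod1 was 2.14-fold lower (1.52 to 3.07) and Neurod4 2.05-fold lower (1.55 to 2.75).

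Genes of axon injury and survival changed in both directions. Of 41 regeneration-associated genes, 9 were called higher and 16 lower, with a median of -0.12 at percentile 9.77, and -0.01 at percentile 37.4 after a correction for GC content and gene length. Ecel1, an endopeptidase induced by axon injury, was 1.86-fold higher (1.68 to 2.05), and Bdnf, a neurotrophin, was 1.65-fold lower (1.30 to 2.10). Of 32 axon growth suppressors, 7 were higher and 6 lower, and Ngfr, the p75 neurotrophin receptor, was 4.32-fold higher (3.38 to 5.56). Of 28 genes of injury-induced death signalling, 8 were higher and 4 lower, and Sarm1, an executor of axon degeneration, was 2.18-fold higher (1.33 to 3.66). Of 33 survival and trophic genes, 7 were higher and 6 lower, and Bcl2l1, an inhibitor of apoptosis, was 2.03-fold higher (1.73 to 2.38). The p53 pathway had 3 members higher and 3 lower of 21.

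In the integrated stress response, 3 of 28 members were called higher and 12 lower, with a median of -0.36 at percentile 0. Nars, an asparaginyl-tRNA synthetase, was 1.5-fold lower (1.44 to 1.57) and Ddit3, which encodes CHOP, 1.48-fold lower (1.33 to 1.65). Of 30 heat shock and chaperone genes, 3 were higher and 13 lower, with a median of -0.23, and -0.10 after the correction. Cryab was 2.35-fold lower (1.44 to 3.95) while Hspa1a was 4.05-fold higher (2.54 to 6.72). Of 19 immediate early genes, 6 were higher and 1 lower, with a median of 0.22 that turned to -0.04 after the correction for GC content and gene length. Junb was 5.30-fold higher (3.67 to 7.84) and Npas4, a factor induced by neuronal activity, 6.52-fold higher (3.20 to 15.0).

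Of 40 synaptic genes, 16 were called higher and 6 lower, with a median of 0.20 at percentile 100, and 0.10 after a correction for GC content and gene length. Syn1, which encodes synapsin I, was 2.35-fold higher (2.11 to 2.62). Neuronal ion channels had 12 of 32 members higher and 2 lower, with a median of 0.26, and 0.10 at percentile 88.2 after the correction. Axon guidance genes had 12 of 39 members higher and 3 lower, with a median of 0.29 at percentile 99.96. After the correction this median was 0.25, still at percentile 99.93. The correction ended camera's call of both lists (adjusted p = 0.34 for ion channels and 0.20 for axon guidance). Without the correction, camera with an estimated correlation called neither list (adjusted p = 0.32 and 0.31), but at that setting it called 0 of the 32 lists. Fscn1, an actin-bundling protein, was 3.09-fold higher (2.48 to 3.88). Of 49 cytoskeleton and growth cone genes, 10 were higher and 16 lower.

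Of 76 cytosolic ribosomal protein genes, 0 were called higher and 17 lower, with a median of -0.27 at percentile 0, and after a correction for GC content and gene length 1 was called higher and 8 lower, with a median of -0.04. These genes share sequence with pseudogenes, and their counts are uncertain. Of 90 nuclear genes of oxidative phosphorylation, 0 were higher and 47 lower, with a median of -0.27, and 4 were higher and 11 lower, with a median of -0.06, after the same correction. The 7 mitochondrial-encoded genes had a median of -0.06 with 0 called, and after the correction a median of 0.33 with 6 called higher. Cholesterol biosynthesis had 1 of 26 genes higher and 8 lower, and Msmo1, a sterol monooxygenase of the pathway, was 1.34-fold lower (1.2 to 1.49). Glycolysis had 8 of 24 genes higher and 6 lower, the small RNA machinery 4 of 20 higher and 1 lower, mTOR and translation control 8 of 30 higher and 2 lower (2 and 1 after the correction), and the cell cycle list 1 of 13 higher and 2 lower. With the correction the medians turned from 0.04 to -0.06 for glycolysis, from -0.01 to 0.06 for the p53 pathway, from -0.07 to 0.05 for the cell cycle and from -0.02 to 0.07 for Müller glia markers, and the survival and trophic median moved from -0.04 to -0.20; camera called none of these 5 lists with or without it. Across genes, which are not independent replicates, the log2 fold change correlated with GC content (Spearman's rho 0.24) and with transcript length (0.28).

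**Figure D2:**
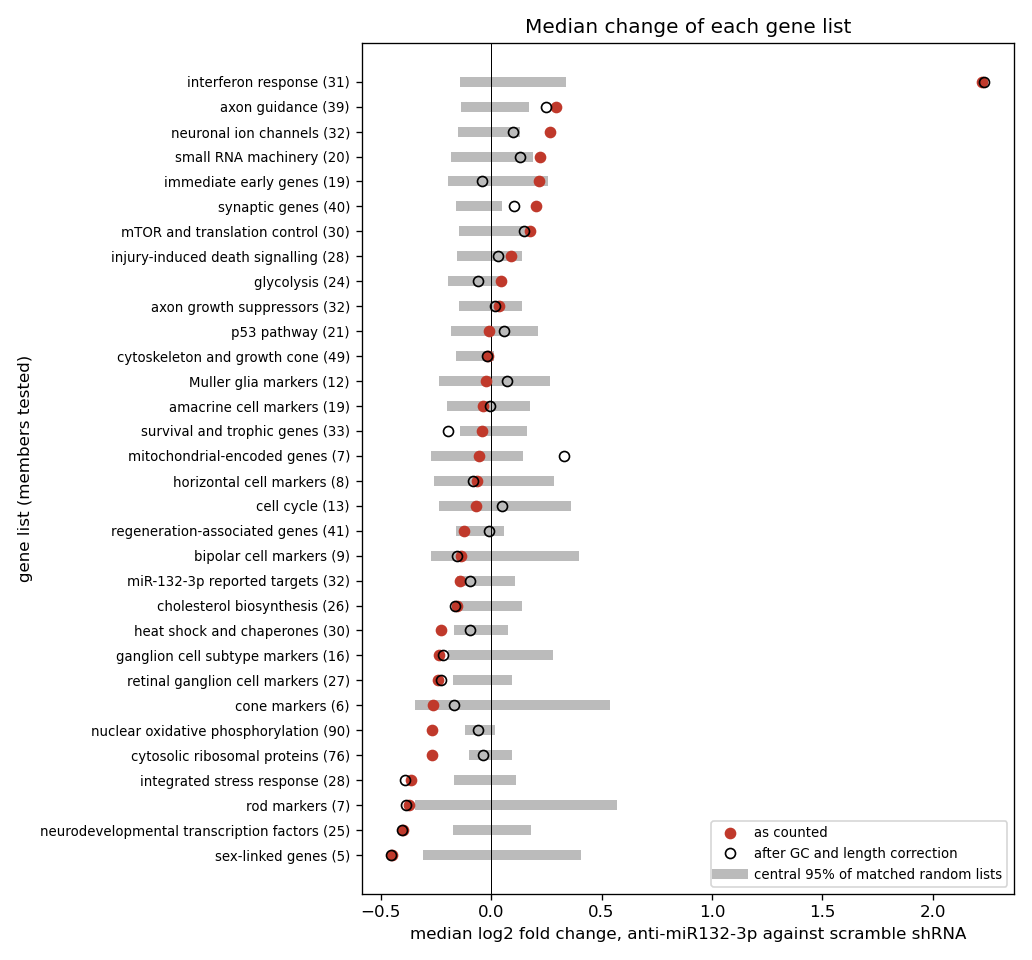
Median log2 fold change of the 32 gene lists with enough tested members (red), the same after the correction for GC content and gene length (open circles), and the central 95% of medians of random lists matched on expression (grey bars). The interferon response lies at 2.22, and the ribosomal protein list moves from -0.27 to -0.04 with the correction.

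Amacrine markers held 3684 CPM with the scramble shRNA and 3918 CPM with the anti-miR132-3p shRNA, beside 5638 and 5234 CPM for ganglion cell markers. Gad2, an enzyme of GABA synthesis, rose from 378 to 521 CPM. Rod markers were at 798 and 568 CPM, of which Gnb1, a G protein subunit not limited to rods, held 2386 of 2946 and 1764 of 1966 counts, and Pdc, a rod phosphoprotein, had 3 counts against 61. The list of other leukocytes, led by Cd74 and H2-Ab1, was at 9.75 and 67.0 CPM. Müller glia markers were at 2498 and 3046 CPM, of which Dkk3 held 3955 of 9223 and 5577 of 10549 counts. Apoe was 3.31-fold higher (2.51 to 4.40) and Slc1a2, a glutamate transporter, 2.10-fold lower (1.21 to 3.76). Astrocyte markers were at 75.0 and 48.5 CPM, cone markers at 156 and 123 CPM, bipolar markers at 349 and 379 CPM, horizontal cell markers at 1255 and 1228 CPM, and endothelial markers at 146 and 154 CPM. Mural and fibroblast markers were at 60.1 and 69.6 CPM, pigment epithelium markers at 46.9 and 45.9 CPM, lens markers at 15.7 and 13.6 CPM, oligodendrocyte markers at 38.2 and 46.5 CPM and erythrocyte markers, led here by genes that neurons also express, at 252 and 199 CPM. Xist, expressed from the inactive X chromosome, was 2.14-fold higher (1.78 to 2.57), and the Y-linked Ddx3y was 1.37-fold lower (1.2 to 1.57). Of 5 sex-linked genes, 1 was called higher and 2 lower, or 1 and 4 when adjusted over the list alone.

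The other lowest genes by the naming rule were Aldh1a1, a retinaldehyde dehydrogenase, 5.61-fold lower (2.63 to 13.7), Ucn, the peptide urocortin, 5.16-fold lower (2.60 to 11.4), and Slc15a2, a peptide transporter, 3.69-fold lower (2.54 to 5.48). Gpnmb was 3.39-fold lower (1.7 to 7.33). Zfp78, Xlr3b, Cfap54, Dnajc21 and Bpifc were between 2.92-fold and 3.28-fold lower.

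Camera with its preset correlation called 13 of the 32 lists, 4 of them higher. With an estimated correlation it called 0, and the smallest adjusted p was 0.15, for the interferon response and for nuclear oxidative phosphorylation. With 2 residual degrees of freedom, a list left uncalled at that setting is not evidence that the list is unchanged.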

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

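The GC and length correction and the summed pairs with an assumed coefficient of variation were added after the data were examined. The main counts were 1540 higher and 1183 lower. With no low-count filter they were 1 and 2, and 0 interferon response members were called; edgeR's prior degrees of freedom fell from 14.1 to 1.16 there. Leaving out 1 library gave 0 to 0 genes higher, 0 to 0 lower and 0 to 0 interferon members; the residual degrees of freedom fell from 2 to 1 and the prior ones to between 1.51 and 1.67, Ifit1 kept log2 fold changes of 4.91 to 5.89 at adjusted p 0.19 to 0.20, and the lone library was assumed to vary like the others. DESeq2's Wald test called 481 higher, 274 lower and 14 interferon members. It gave no adjusted p for 1551 genes, among them Irf7, Ifi44, Gbp2 and Rtp4 of the interferon list. A 2-fold minimum left 451 and 92, and glmTreat against 1.2-fold left 734 and 219. With each pair summed, an assumed coefficient of variation of 0.1 gave 415 higher and 47 lower, 0.2 gave 43 and 6 with 17 interferon members, and 0.4 gave 6 and 1 with 3 interferon members. Other than by construction, the cause was not tested. The remaining scaling, filter, test, threshold and depth settings stayed within 1.5 times of both counts. The GC and length correction gave 1248 and 848, of which 1026 and 658 were shared with the main calls, and 15 genes were called in the opposite direction.

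Camera called 13 lists, 0 with an estimated correlation, where the interferon median of 2.22 had an adjusted p of 0.15, and fry called 20. The reported targets, at -0.14, passed with fry (-0.14, adjusted p 0.021) and with the GC and length correction (-0.10, adjusted p 0.042); over the other settings the adjusted p ran from 0.057 to 0.32. The seed-match shift of -0.030 moved inside the central 95% of matched sets with the 8mer alone (-0.022) and with at least 2 sites (-0.037). These sets held 320 and 202 genes in place of 1467. The central 95% of matched medians was wider, -0.025 to 0.070 and -0.024 to 0.090, against 0.014 to 0.061 for all 1467. With at least 2 sites the shift was larger in size than the main one, so the wider range placed it inside. The shift also moved inside with matching on 3' UTR length and GC content but not expression (-0.0101). It did so too with the GC and length correction (-0.0092). For the matching on GC content and the correction the cause was not tested. The correction turned mt-Co1 to 0.33, Stmn1 to 0.14 and the median of the mitochondrial-encoded list to 0.33; the cause was not tested.

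With the replicate block 1740 genes were higher and 1437 lower. With 2 numbers and no label for what they mark, and deviations that correlated at 0.01, the libraries share only a number.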

Other observations

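The prediction on seed matches was written before its result, and the other tests below were chosen after their results were seen. With each pair summed and a coefficient of variation of 0.2 assumed between samples, 43 genes were higher, of which 17 are on the interferon list. Those outside it include Gbp2b, Iigp1, Cd74, Ctss and Cxcl13, described above. The fixed list does not hold every interferon-induced gene, as Iigp1 shows, so the genes outside it are not a separate response. Others outside it, named after their values were seen, include Gbp7, Gbp9, Ifi47, Ifi202b, Uba7, Cd274 and the immunoglobulin gene Igkv6-32. Also among them were Tgfbi (log2 fold change 3.31), Fxyd7, a regulator of the sodium pump (3.15), Trp53i11 (3.13), Impdh1 (2.38) and Diras1 (1.77).

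The 2 libraries of a group agreed within sampling noise. The values are those that parts of one read set or one library would give, with a highest chi-square per degree of freedom of 1.02, where the pairs across groups reached 4.03. Separately sorted cells with little variation may give the same, as the lowest value of 1.00 does not decide between them. No biological explanation was tested.

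Interferon response genes were higher with the anti-miR132-3p shRNA. A trend with GC content or length is argued against, since the list's median was 2.23 after the correction. Seed matches of miR-132-3p were found in the annotated 3' UTR of 3 of 31 members, 9.68%, against 14.1% of other genes. Direct targeting through such a match is argued against only for the members without one. The comparison with other genes showed no difference (Fisher's exact test, two-sided, p = 0.61). It cannot decide on targeting, since most gene lists would hold few matches. Microglia or other leukocytes among the sorted cells may contribute despite the sort for mCherry, which stays open because the marker sets disagree, with 45 markers 5.58-fold higher, 47 markers 2.2-fold higher and the whole microglia list at 290 against 294 CPM, beside a median of 4.67-fold for the interferon list. Differences between vector preparations, injections or animals stay open, because the design has 1 sample per group. Xist was 2.14-fold higher, and the Y-linked Ddx3y and Eif2s3y were 1.37-fold and 1.33-fold lower, as pools with a different mix of sexes would give. Such a difference could not be told apart from an effect of the vector.

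Of 76 ribosomal protein genes 17 were called lower and of 90 oxidative phosphorylation genes 47. With an estimated correlation camera called neither list (adjusted p = 0.20 and 0.15), but it called 0 of all 32 lists there and so cannot decide. After the GC and length correction the ribosomal protein median was -0.036, at percentile 4.93 of matched lists, and camera did not call the list (adjusted p = 0.27). A GC or length trend would give this, but the correction cannot identify the source. It removes any change that short transcripts share, and these genes had a median transcript length of 910 bases against 3213 for all tested genes. For oxidative phosphorylation the median was -0.060, at percentile 1.59, and camera still called the list lower (adjusted p = 0.045). These values do not settle whether the trend could account for all of the decrease, and what produced the trend was not tested.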
